A study of Mus musculus with 6 samples.

How the data were processed

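Stranded libraries from total RNA of mouse bone marrow neutrophils were sequenced, with 3 libraries per group. Per the submitters' processing notes the tools were Trim Galore, Subread and featureCounts on the mm10 build, with versions not given in the sources used here. The deposited table gave, per the file headers, a raw count, a TPM and an FPKM value per gene and library, for 51826 gene rows with symbols and positions. The deposited counts were whole numbers with no normalization. The deposited TPM values summed to between 999842 and 999905 per library. The deposited FPKM values were proportional to TPM within a library and were not used further. Even values were over-represented among low counts (55.5 to 57.9% of them), and the cause was not tested. Positions equalled those of the GENCODE M21 annotation for 48619 rows, and 193 IDs were not in it. All genes whose coordinates are given are protein-coding in that annotation. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain. For a symbol with several gene IDs, the ID with the most counts was used.

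Total counts were 37346055, 37643383, 38826701 in Ctrl_MV replicates 1, 2 and 3 and 39059806, 38117403, 42043434 in KD_MV replicates 1, 2 and 3. Within groups the chi-square per degree of freedom between libraries ran from 21.9 to 107, so no pair looked like the same library deposited again.

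Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and total of 15, TMM factors, glmQLFit and glmQLFTest on group, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), leaving 16071 genes. Printed CPM are TMM-scaled. Standard errors are the absolute log2 fold change over the square root of F. The comparison, tests, named genes rule and 44 gene lists were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, at least 5 members) and fry in limma 3.58.1. Named genes were Ezr, the 12 largest rises and falls among called genes with non-overlapping groups and mean CPM of at least 5 (leaving out clone names, receptor segments and pseudogenes), and the 4 members with the smallest p of each list called or with at least 3 called members. That rule gave 175 genes, of which the text gives a part.

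Alternatives were RLE, upper-quartile and library-size scaling, no filter or a stricter filter (CPM of at least 1 in 3 libraries), limma-voom, DESeq2 1.42.0, a fold threshold of 1.5, adjusted p of 0.1 or 0.01, a replicate block, leaving out each library, leaving out mitochondrial and ribosomal protein genes, and camera with an estimated correlation or on ranks. Halved counts, leaving out hemoglobin genes, and limma on log2(TPM + 1) with mean TPM of at least 1 were added after seeing the data. Alternatives meant for normalized values alone did not apply, since counts were available.

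The pipeline was tested on simulated counts for this comparison, in which 200 genes were changed before filtering and 15743 genes passed the filter. It recovered 12.5% of 1.5-fold, 61.3% of 2-fold and 95.2% of 4-fold changes, with 8 calls among the 15554 unchanged genes tested. Only 200 genes were changed and genes were drawn independently, whereas 8459 of 16071 genes were called in the data. These rates therefore do not carry over to the real comparison. With the 200 scattered changes camera called 0 of 44 lists. In another simulation over 15758 genes, only the members of the NF-kB target list were raised, by 1 on the log2 scale, and camera called 5 of 44 lists. Of the 4 others, 3 shared members with it (aged or activated neutrophil genes, N1-associated genes and apoptosis regulators), and the mitochondrially encoded list shared 0, so its call there was false. Calls of overlapping lists are therefore not independent of each other.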

Results

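RNA was sequenced from neutrophils isolated from mouse bone marrow and exposed to microvesicles, the small membrane particles that cells shed. The particles came from Hepa1-6, a mouse hepatoma cell line, deprived of glucose before collection. In 3 libraries the donor cells were wild type (Ctrl_MV) and in 3 libraries their ezrin had been knocked down (KD_MV). The only factor that the labels name was which microvesicles the neutrophils received. Any difference in cell preparation between the groups cannot be told apart from it. Log2 fold changes are KD_MV minus Ctrl_MV. Total counts ran from 37346055 to 42043434 per library. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

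Ezr, the gene targeted in the vesicle donors, was measured here in the recipient neutrophils and therefore checks no label. Its levels were 382, 354 and 342 CPM (counts scaled to library size with TMM factors) in Ctrl_MV replicates 1, 2 and 3, and 353, 359 and 428 CPM in KD_MV replicates 1, 2 and 3. The difference for Ezr did not pass the test (log2 fold change 0.08 ± 0.11 (SE), adjusted p = 0.569), but with library size as the only scaling it did (log2 fold change 0.48, adjusted p = 0.00426), as it did with limma on log2(TPM + 1) (difference 0.65, adjusted p = 0.00192).

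The comparison asked how neutrophil transcription differed between the 2 kinds of microvesicles. Most measured genes of proliferation, cholesterol synthesis, the heat shock response and primary granules were higher in libraries of neutrophil preparations given knockdown microvesicles. Most inflammatory cytokine, NF-kB target and erythroid genes were lower. Whether these changes arose within neutrophils or from the mix of cells was not settled. Counts for each list follow, and each list call was lost when camera used an estimated correlation (smallest adjusted p = 0.0593). In edgeR's quasi-likelihood test 8459 of 16071 tested genes passed an adjusted p of 0.05, of which 4464 were higher and 3995 lower. Among these, 2172 rose and 1607 fell by more than 1 on the log2 scale. The groups did not overlap in 9853 tested genes, or 61.3%, where chance gives 10%. The split by direction depended on scaling: 52.8% of calls were higher with TMM factors and 78.8% with library size only, which moved the median gene by 0.40 on the log2 scale, so small changes are relative to that shift. Hemoglobin transcripts took 9.96% of counts in Ctrl_MV and 1.09% in KD_MV, and each gene group described here moved with that difference in composition.

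The eosinophil ribonuclease genes Ear1 (chromosome 14, 43818765 to 43875517, mm10) and Ear2 (chromosome 14, 44102654 to 44103534) had the largest rises by the naming rule. Ear1 went from 0.326 ± 0.191 to 78.3 ± 15.1 CPM (SD, n = 3 per group; log2 fold change 7.90 ± 0.33 (SE), adjusted p = 1.08e-06) and Ear2 from 0.323 ± 0.192 to 71.9 ± 3.75 CPM (log2 fold change 7.78 ± 0.27 (SE), adjusted p = 4.43e-07). Both belong to a family of close paralogs, so their separate counts are uncertain. Epx, eosinophil peroxidase (chromosome 11, 87864000 to 87875536), rose from 3.1 ± 0.245 to 75.7 ± 8.06 CPM (log2 fold change 4.61 ± 0.14 (SE), adjusted p = 2.47e-07), and Prg2, eosinophil major basic protein, rose from 12.7 ± 1.85 to 274 ± 73.2 CPM (log2 fold change 4.43 ± 0.23 (SE), adjusted p = 2.47e-06). In the list of eosinophil, basophil and mast cell markers, 8 of 16 measured members rose and 2 fell, or 10 rose and 2 fell adjusted over the list alone. Camera gave an adjusted p of 1.11e-10, and with an estimated correlation adjusted p = 0.0593. The chemokine gene Cxcl9 rose from 0.405 ± 0.0677 to 14.9 ± 3.97 CPM (log2 fold change 5.19 ± 0.27 (SE), adjusted p = 2.38e-06).

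Most measured proliferation genes rose. Uhrf1, a maintenance methylation cofactor (chromosome 17, 56303321 to 56323486), rose from 7.59 ± 0.591 to 170.4 ± 12.3 CPM (log2 fold change 4.49 ± 0.12 (SE), adjusted p = 2.47e-07). The genes Pclaf (4.86), Gins2 (4.52), Clspn (4.29), Dtl (4.61) and Exo1 (4.66), which act in DNA replication or repair, rose as well (log2 fold changes in parentheses, here and for later genes). Of the fixed proliferation list 26 of 31 measured members rose and 1 fell, or 27 rose and 1 fell adjusted over the list alone. The list as a whole had a camera adjusted p of 2.42e-26, and with an estimated correlation adjusted p = 0.0593. Mcm6, a subunit of the replicative helicase, rose from 19.1 ± 1.52 to 249 ± 3.59 CPM (log2 fold change 3.70 ± 0.11 (SE), adjusted p = 2.47e-07), with Mcm5 (3.41), Mcm7 (2.81) and Rrm2 (2.73) beside it. The proliferation marker Mki67, chosen after its value was seen, did not pass (log2 fold change 0.16 ± 0.23 (SE), adjusted p = 0.588).

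Most measured cholesterol synthesis genes rose. For this list 20 of 24 measured members rose and 0 fell, or 20 rose and 0 fell adjusted over the list alone. Tested with camera, the adjusted p was 4.10e-13, and with an estimated correlation adjusted p = 0.0593. Fdps, farnesyl diphosphate synthase (chromosome 3, 89093588 to 89101959), rose from 11.4 ± 1.97 to 84.2 ± 10.3 CPM (log2 fold change 2.89 ± 0.16 (SE), adjusted p = 2.97e-06), with Hsd17b7 (2.93) and Idi1 (2.29). The annotation marks the Fdps locus as overlapping another gene, so its count is uncertain. Soat2, which esterifies cholesterol, moved the other way, from 145 ± 7.16 to 4.43 ± 0.884 CPM (log2 fold change -5.03 ± 0.17 (SE), adjusted p = 3.73e-07). Soat2 (chromosome 15, 102150526 to 102163474) lies beside Igfbp6 (chromosome 15, 102144362 to 102149511), which also fell (-4.46). Heat shock genes also rose, 13 of 15 with 0 falling, or 13 rose and 0 fell adjusted over the list alone. For the whole list, camera gave an adjusted p of 3.27e-09, and with an estimated correlation adjusted p = 0.0593. They included the chaperones Hsph1 (2.25), Hspa8 (1.71), Hspe1 (1.61) and Fkbp4 (1.97).

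Stress response genes were among the largest falls. Chac1, a glutathione-degrading enzyme (chromosome 2, 119351229 to 119354381), fell from 93.6 ± 5.8 to 1.58 ± 0.266 CPM (log2 fold change -5.89 ± 0.15 (SE), adjusted p = 2.47e-07) and Trib3, a stress-induced pseudokinase, from 263 ± 11.3 to 10.5 ± 3.35 CPM (log2 fold change -4.65 ± 0.24 (SE), adjusted p = 2.42e-06). The transcription factor Atf4 fell from 1027 ± 50.3 to 256 ± 11.3 CPM (log2 fold change -2.00 ± 0.10 (SE), adjusted p = 2.06e-06), and Atf5 (-4.60), Ddit3 (-2.39), Asns (-3.10) and Sesn2 (-3.33) fell too. The unfolded protein and integrated stress response list moved both ways: 13 of 26 measured members fell and 10 rose, or 10 rose and 14 fell adjusted over the list alone. The adjusted p from camera was 9.04e-04, and with an estimated correlation adjusted p = 0.125. The call was lost without a filter (adjusted p = 0.133), with limma-voom (0.249) and on ranks (0.489), and with library size only the list median turned to 0.14. Its ER chaperone and folding members Sdf2l1 (3.04), Pdia4 (2.17) and Calr (1.51), chosen after their values were seen, rose. Of the ferroptosis and glutathione list 15 of 21 measured members fell and 2 rose, or 3 rose and 15 fell adjusted over the list alone. Camera gave an adjusted p of 7.26e-09, and with an estimated correlation adjusted p = 0.0593. The cystine transporter subunits Slc7a11 (-1.91) and Slc3a2 (-1.98) were among them. Cyp1a1, a cytochrome P450 of the aryl hydrocarbon response (chromosome 9, 57687928 to 57703824), fell from 10.9 ± 2.19 to 0.242 ± 0.0625 CPM (log2 fold change -5.47 ± 0.26 (SE), adjusted p = 1.79e-06). Other named falls were Angptl6 (-5.15), Slc7a3 (-4.93), Igfbp6 (-4.46), Cox6a2 (-4.45), Cth (-4.41), Ermn (-4.33) and Fam129a (-4.04).

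Most inflammatory cytokine and chemokine genes fell: 23 of 32 measured members fell and 3 rose, or 3 rose and 26 fell adjusted over the list alone. The chemokine gene Cxcl9 (5.19), described above, was among the 3 that rose. The list as a whole had a camera adjusted p of 2.28e-11, and with an estimated correlation adjusted p = 0.0766. Il6 fell from 126 ± 25.2 to 13.5 ± 1.19 CPM (log2 fold change -3.22 ± 0.17 (SE), adjusted p = 2.42e-06), Il23a from 32.6 ± 2.08 to 2.72 ± 0.649 CPM (log2 fold change -3.58 ± 0.18 (SE), adjusted p = 2.42e-06), and the abundant neutrophil chemokine Cxcl2 from 10505 ± 729.8 to 2721 ± 392 CPM (log2 fold change -1.95 ± 0.15 (SE), adjusted p = 1.54e-05). NF-kB targets fell likewise, since 25 of 30 measured members fell and 1 rose, or 1 rose and 25 fell adjusted over the list alone. Tested with camera, the adjusted p was 5.73e-09, and with an estimated correlation adjusted p = 0.0767. Among them were Ptgs2 (-1.96), Ier3 (-1.44), Nfkbiz (-1.21) and Birc3 (-1.04). Among immediate early genes 18 of 27 measured members fell and 2 rose, or 2 rose and 18 fell adjusted over the list alone. For the whole list, camera gave an adjusted p of 1.22e-05, and with an estimated correlation adjusted p = 0.0593. With library size only, 16 fell and 6 rose.

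**Figure D1:**
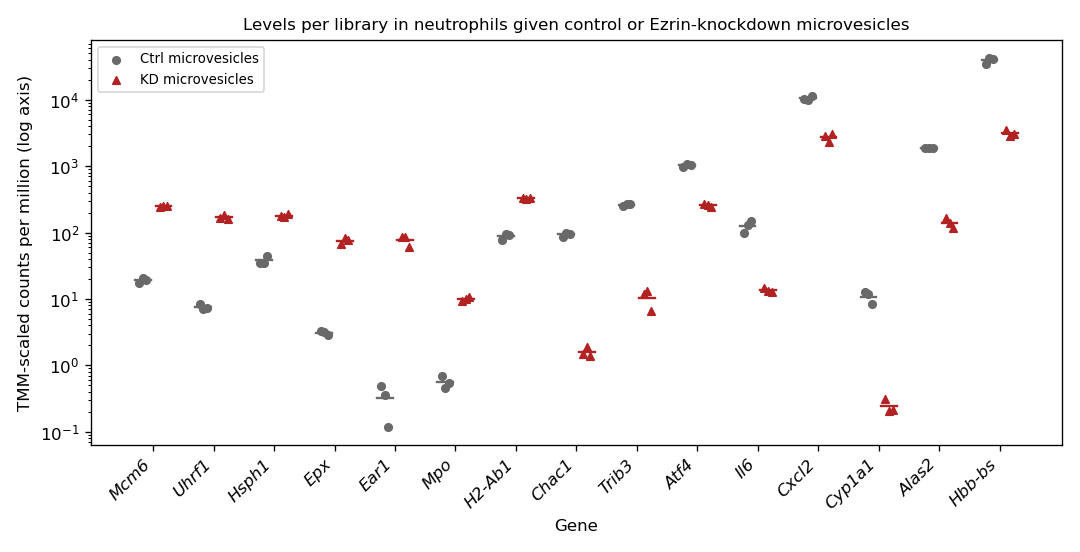
TMM-scaled CPM on a log axis for 15 named genes in each of 3 Ctrl_MV (circles) and 3 KD_MV (triangles) libraries, with group means as bars. The groups do not overlap for any gene shown. That was a condition for naming the largest rises and falls, so for those genes it is no separate evidence.

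Lists describing neutrophil state shared members with the lists above. In the mature neutrophil list 16 of 23 measured members fell and 2 rose, or 2 rose and 16 fell adjusted over the list alone. The adjusted p from camera was 2.70e-05, and with an estimated correlation adjusted p = 0.0766. The formyl peptide receptor Fpr1 went from 1842 ± 89 to 552 ± 38.3 CPM (log2 fold change -1.74 ± 0.11 (SE), adjusted p = 6.02e-06). For aged or activated neutrophil genes 12 of 17 measured members fell and 1 rose. Camera gave an adjusted p of 9.40e-06, and with an estimated correlation adjusted p = 0.0766. With library size only, 10 aged or activated genes fell and 4 rose, with a median of -0.61 in place of -1.02. For mature neutrophil genes 12 then fell and 4 rose, with a median of -0.40 in place of -0.80. The N2-associated list gave 13 lower and 2 higher of 20. The list as a whole had a camera adjusted p of 5.27e-07, and with an estimated correlation adjusted p = 0.0593. It included Vegfa, an angiogenic factor (-2.11), among the falls. Arg1 was among the 2 that rose (3.03), at low levels (0.434 to 3.58 CPM). The PMN-MDSC list gave 14 lower and 3 higher of 25, with Arg1 also among the higher. Tested with camera, the adjusted p was 4.04e-06, and with an estimated correlation adjusted p = 0.0811. With library size only that list gave 13 lower and 7 higher, with a median of -0.35 in place of -0.75. The N1-associated list was not called, at 7 lower and 3 higher of 14 (camera adjusted p = 0.136), but was called downward without a filter (adjusted p = 0.0202), with limma-voom (0.0452) and on ranks (0.0496). Of its members, Cxcl9 (5.19) and Tnfsf10 (1.90) were among the 3 that rose. Il12b (-1.87) and Icam1 (-0.94) were among the 7 that fell. Whether the N1 list differed from the N2 list was not tested. Adjusted over the list alone, the counts were 12 lower and 2 higher for aged or activated genes, 14 lower and 2 higher for the N2 list, 14 lower and 3 higher for the PMN-MDSC list and 7 lower and 3 higher for the N1 list.

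Adhesion and chemotactic receptor genes fell in 19 of 27 cases. For the whole list, camera gave an adjusted p of 1.53e-05, and with an estimated correlation adjusted p = 0.0766. Phagocytosis genes fell in 11 of 17 cases. The adjusted p from camera was 9.04e-04, and with an estimated correlation adjusted p = 0.0766. With library size only, 12 receptor genes fell and 6 rose, and 7 phagocytosis genes fell and 3 rose. Lysosome genes fell in 22 of 29. Camera gave an adjusted p of 1.19e-06, and with an estimated correlation adjusted p = 0.181. Apoptosis regulators fell in 15 of 24 cases and rose in 3. The list as a whole had a camera adjusted p of 6.47e-05, and with an estimated correlation adjusted p = 0.125. With library size only, 12 of them fell and 5 rose. Neutrophil transcription factors fell in 8 of 17. Tested with camera, the adjusted p was 0.0356, and with an estimated correlation adjusted p = 0.157. This call was lost with library size only, where 7 fell and 6 rose and the list median became 0.05, and with limma-voom (adjusted p = 0.0582) or camera on ranks (0.0613). Primary granule genes, made by neutrophil precursors, rose in 8 of 10 cases. For the whole list, camera gave an adjusted p of 9.54e-05, and with an estimated correlation adjusted p = 0.0614. Mpo went from 0.557 ± 0.115 to 9.95 ± 0.8 CPM (log2 fold change 4.15 ± 0.20 (SE), adjusted p = 1.79e-06), and Prtn3 (4.29), Elane (4.01) and Ms4a3 (2.93) rose beside it, all at low levels. MHC class II and antigen presentation genes rose in 9 of 18 cases. The adjusted p from camera was 0.0188, and with an estimated correlation adjusted p = 0.317. The call was lost with limma-voom (adjusted p = 0.0966) and on ranks (0.115). The class II genes H2-Eb1 (2.05), H2-Aa (2.02) and H2-Ab1 (1.90) rose, whereas Cd80, a costimulatory ligand, fell (-2.33). B-lineage markers, from cells that also express class II genes, moved with them, 10 of 16 being higher, among them Cd22 (2.49) and Ms4a1 (1.21). Adjusted over the list alone, the counts were 19 lower and 2 higher for receptors, 12 lower and 2 higher for phagocytosis, 25 lower and 0 higher for lysosome, 15 lower and 3 higher for apoptosis, 8 lower and 2 higher for transcription factors, 1 lower and 8 higher for primary granules and 3 lower and 10 higher for antigen presentation.

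Several lists of markers of other cell types moved with the groups, and hemoglobin transcripts were abundant. The 4 hemoglobin genes took 9.96 ± 0.878% of counts in Ctrl_MV and 1.09 ± 0.0782% in KD_MV (SD, n = 3 per group; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of the erythroid markers 11 of 16 measured members fell and 0 rose, or 0 rose and 11 fell adjusted over the list alone. Camera gave an adjusted p of 8.16e-17, and with an estimated correlation adjusted p = 0.0593. With the 4 hemoglobin genes left out, 7 of 12 fell. Alas2, the erythroid heme synthesis enzyme (chromosome X, 150547375 to 150570638), fell from 1896 ± 10.9 to 139 ± 23.3 CPM (log2 fold change -3.76 ± 0.15 (SE), adjusted p = 9.44e-07). The hemoglobin genes Hba-a1 (-3.54), Hba-a2 (-3.56) and Hbb-bs (-3.65) fell too, and their individual counts are uncertain because each has a near-identical copy. B-lineage markers rose in 10 of 16 cases. The list as a whole had a camera adjusted p of 0.0152, and with an estimated correlation adjusted p = 0.413. Among them were Cd22 (2.49), Ms4a1 (1.21), Pax5 (1.16) and Cd79a (0.95). Megakaryocyte and platelet markers rose in 8 of 11. Tested with camera, the adjusted p was 0.00703, and with an estimated correlation adjusted p = 0.265. Hepatocyte and hepatoma genes, markers of the vesicle donors, fell in 7 of 10 measured cases. Only these 10 of the 30 listed genes were tested. For the whole list, camera gave an adjusted p of 0.0485, and with an estimated correlation adjusted p = 0.361. Afp went from 26.5 ± 6.4 to 7.75 ± 1.52 CPM (log2 fold change -1.78 ± 0.21 (SE), adjusted p = 1.54e-04). The list call was lost with RLE scaling (adjusted p = 0.0531), a stricter filter (0.0677) and halved counts (0.076). It was also lost without KD_MV replicate 2 (0.0728), KD_MV replicate 3 (0.108) or Ctrl_MV replicate 2 (0.0591). With the stricter filter 3 of 4 hepatoma genes tested fell. Adjusted over the list alone, the counts were 3 lower and 10 higher for B-lineage markers, 1 lower and 9 higher for megakaryocyte markers and 7 lower and 1 higher for hepatoma genes.

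Oxidative phosphorylation genes rose in 37 of 74 cases. The adjusted p from camera was 0.00113, and with an estimated correlation adjusted p = 0.72. The number higher was 61 without KD_MV replicate 3, 25 to 31 with any other library left out and 66 with library size only. Ribosomal protein genes rose in 32 of 74 cases. Camera gave an adjusted p of 0.00302, and with an estimated correlation adjusted p = 0.739. Here the number higher was 59 without KD_MV replicate 3, 25 to 30 with any other library left out and 65 with library size only. Mitochondrially encoded genes rose in 12 of 15. The list as a whole had a camera adjusted p of 0.0252, and with an estimated correlation adjusted p = 0.72. The number higher was 6 without Ctrl_MV replicate 1, and the list median went from 1.26 to 0.67 without KD_MV replicate 3. The mitochondrial list call was lost with library size only (adjusted p = 0.0966). Camera also called this list in a simulation in which its genes were unchanged. The fry adjusted p was 0.0534 for oxidative phosphorylation, 0.0732 for ribosomal protein and 0.0979 for mitochondrially encoded genes. These 3 fry tests did not pass. Adjusted over the list alone, the counts were 1 lower and 37 higher for oxidative phosphorylation, 0 lower and 32 higher for ribosomal protein genes and 1 lower and 12 higher for mitochondrially encoded genes. KD_MV replicate 3 carried 3.49% mitochondrial counts against 1.6% and 1.51% in KD_MV replicates 1 and 2. Xist and the Y-linked gene Ddx3y were both detected in every library. Both were lower in KD_MV in edgeR's test (Ddx3y -0.91, adjusted p = 0.00244, and Xist -0.51, adjusted p = 0.00341). Of 5 sex-linked genes tested, 3 were called lower and 0 higher. With library size only Xist did not pass (adjusted p = 0.386).

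No list call was made for interferon-stimulated genes (camera adjusted p = 0.366), glycolysis (0.563), hypoxia (0.366), secondary granule (0.29), extracellular trap (0.649), NADPH oxidase (0.0931), monocyte (0.662) or ezrin-radixin-moesin genes (0.818). The NADPH oxidase list was called downward without a filter (adjusted p = 0.00493), with limma-voom (0.0227), on ranks (0.0216) and without KD_MV replicate 3 (0.0462). The lists for cholesterol efflux (0.563), T and NK cells (0.723), dendritic cells (0.14), progenitors (0.252), stroma (0.452), histones (0.649), sex-linked genes (0.249) and fatty acids (0.737) were not called either. The median, mean and test differed in sign in 3 of these lists. The fatty acid list had a median of -0.17, a mean of 0.04 and a test directed upward. The median and mean were -0.23 and 0.02 for glycolysis and 0.05 and -0.06 for secondary granules, both with a test directed downward. In all, camera called 27 of 44 lists, 11 upward and 16 downward, and 0 with an estimated correlation, where the smallest adjusted p was 0.0593. fry, which tests whether a list moves on balance in a direction, called 32.

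**Figure D2:**
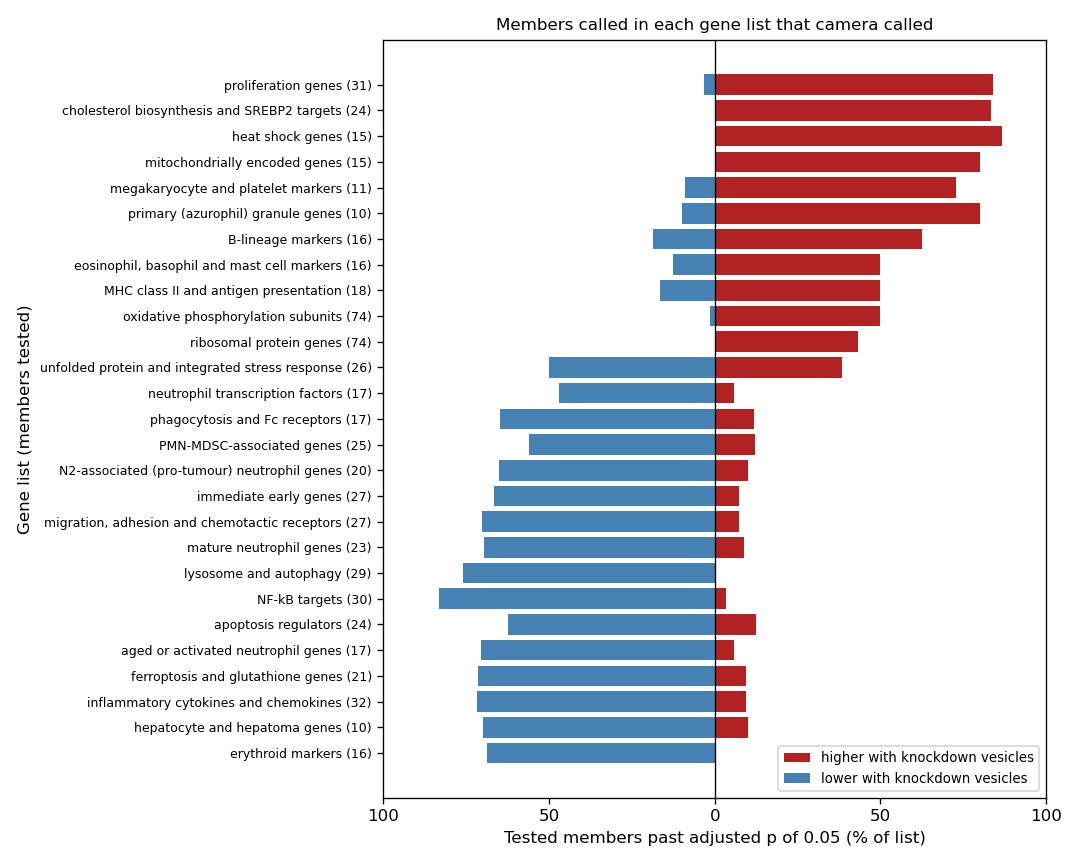
Share of measured members past adjusted p of 0.05 in each of the 27 lists that camera called with its preset correlation, lower to the left and higher to the right, with the number measured in parentheses. No list was called with an estimated correlation.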

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

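The halved counts, the omission of hemoglobin genes and the TPM test were chosen after seeing the data. Over the alternatives, 3114 values of named genes kept direction and side of the threshold, 14 lost the call, 2 gained it and 4 changed sign. For lists, 699 values stayed on the same side of the threshold, whether called or not, 42 lost the call and 7 gained it. Most of the losses came with an estimated correlation, where the number of lists changed was 0 against 27. With library size only, 7455 genes were higher and 2010 lower, and Eif2s3y went to 0.22. On TPM, 7719 were higher and 1228 lower (86.3% higher, with a median shift of 0.53), Pecam1 went to 0.13 and Eif2s3y to 0.38. The TPM test also changed the model and the gene filter, and the cause of these shifts was not tested. A tested fold of at least 1.5 left 3885 genes, 2180 higher and 1705 lower, by its construction. Leaving out each library gave 7290 to 8710 genes changed, 3809 to 4494 higher, 3478 to 4216 lower and 26 to 27 lists. Ezr ran from -0.0198 to 0.13. It changed sign without KD_MV replicate 3, whose level of 428 CPM was the highest of the 6 libraries. Why Ezr was higher in that library was not tested. DESeq2 called 8449 genes and limma-voom 8466.

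With the replicate number as a block, 7799 genes changed, 4123 higher and 3676 lower, with 27 lists. Deviations of same-numbered libraries correlated at -0.01, -0.08, -0.05, and those of differently numbered libraries at -0.03 to 0.09. No shared effect of the replicate number was visible. Whether same-numbered libraries were prepared together is not given in the sources used here.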

Other observations

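These gene lists were written after the top genes had been seen, so their tests are not independent evidence. Their p-values were adjusted over the added lists alone, which are fewer than the fixed lists. Passing here is therefore an easier condition and does not set these lists apart from the fixed lists. For the fixed proliferation list, camera with an estimated correlation gave an unadjusted p of 0.00206, and 0.0593 adjusted over the fixed lists. In a list of amino acid supply genes and other Atf4 targets, 20 of 24 fell and 1 rose (median log2 fold change -2.15, adjusted p = 0.0099 with an estimated correlation in camera), with the transporters Slc1a4 (-3.73), Slc6a9 (-3.24) and Slc7a5 (-2.29) and the folate enzyme Mthfd2 (-2.36) lower. The falls included Atf4 targets outside amino acid supply, such as Cebpg (-2.34), Nupr1 (-2.29), Eif4ebp1 (-1.86) and Ddit4 (-1.39), and the rise was that of the cysteine synthesis enzyme Cbs, from 0.395 ± 0.0832 to 0.733 ± 0.101 CPM (log2 fold change 0.89 ± 0.31 (SE), adjusted p = 0.0406). Aminoacyl-tRNA synthetase genes split, 12 of 20 falling and 6 rising (adjusted p = 0.316 with an estimated correlation), with Aars (-1.61), Sars (-1.39) and Cars (-1.31) lower and Kars (1.25), Qars (0.99) and Hars (0.96) higher. Aryl hydrocarbon receptor targets fell in 7 of 7 cases (adjusted p = 0.0134 with an estimated correlation), including Cyp1b1 (-3.34), Tiparp (-1.31) and Ahrr (-1.28). Replication origin and fork genes rose in 33 of 33 cases (median 2.41, adjusted p = 8.27e-04 with an estimated correlation), with Chaf1a (4.16), Lig1 (4.10) and Pole (3.96). Chaperonin, HSP90 co-chaperone and HSP70 genes rose in 12 of 18 cases and fell in 2 (adjusted p = 0.316 with an estimated correlation), with the mitochondrial chaperone Hspa9 (-1.63) falling.

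Of the tests below, those on scaling, on the Ear paralogs, on dilution, on the second erythroid list and on eosinophil surface genes were chosen or had members seen beforehand. The erythroid test list held Hbq1a, whose value was already known. The tests on the mitochondria-rich library and on the splits were written before their results.

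Hemoglobin genes were lower with knockdown vesicles. Scaling does not account for this: with library size only, the median log2 fold change of the 4 genes was still -3.18. Fewer erythroid cells, or less of their RNA, may explain it, since 15 of 18 genes of a second late erythroid list were lower by sign and 11 passed the test, but their median of -0.68 (-0.66 without Hbq1a) lies between the bounds set for and against, so erythroid share and RNA content per cell remain open. A response of these cells to the vesicles was not tested.

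Eosinophil granule genes were higher with knockdown vesicles. Reads shared between Ear paralogs cannot account for the rise of Epx and Prg2, which lie outside that family and had a median of 4.52. Both had already been seen among the largest rises. How far shared reads affect the Ear genes themselves was not tested. More eosinophils of all stages is argued against by eosinophil surface genes, whose median over 6 genes was 0.18 with none above 0.60 (Siglecf), though several were low. A rise in early eosinophil precursors, or in granule gene transcription, could still explain it as a hypothesis and was not tested.

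Most inflammatory cytokine genes were lower with knockdown vesicles. With library size only the list median remained -0.72, and without the mitochondria-rich KD_MV replicate 3 all 23 of 23 falling members were still called lower. Even dilution by all other cell types would raise their markers alike. The B-lineage and erythroid medians differed by 2.21 on the log2 scale, however (p = 5.00e-05, 100000 permutations of genes between the lists). That p was made a condition after its value was seen, and it treats genes as independent although the estimated correlations were 0.253 and 0.133 within the B-lineage and erythroid lists. More of some cell types with fewer erythroid cells would also give unequal medians, so a lower neutrophil share is not excluded. A weaker response of the neutrophils to knockdown vesicles may explain the pattern, as a hypothesis that was not tested. No library came from neutrophils left without vesicles, so these data cannot show a response to either kind. Differences in cell preparation between the groups stay open.

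The real split gave 8459 genes, and the highest of the other splits gave 0 in edgeR's test (at most 282 at an unadjusted p under 0.05, and 0 with limma-voom). Each other split puts libraries of both groups on each side, so the group difference widens the spread within its sides. Few calls follow from that alone, so these splits give no reference for chance. Only 1 of the 10 splits of the 6 libraries gave as many genes, and 10 splits are too few for a share under 0.05.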
